A study of Mus musculus with 8 samples.

How the data were processed

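Per the labels' protocols, nuclei of adult mouse midbrain were isolated, sorted by FACS and made into 10x Chromium Single Cell 3' v3 libraries. The 8 samples are 4 flow cell lanes of 2 pools of 3 mice, 1 per genotype. The submitters' processing notes name Cell Ranger 3.1.0 and build mm10 without saying what each was used for. The authors deposited 1 table of raw UMI counts per gene and nucleus, with 23481 genes and 5740 nuclei. The counts are whole numbers and are not normalised, and the genotype of each nucleus was read from the start of its column name. Lanes of a library are not kept apart in the table. Which nuclei and genes were removed before deposit is not stated; no nucleus had under 500 genes or over 5% mitochondrial counts. The lowest and highest totals were 673 and 121160 UMIs in the wt and 621 and 127151 UMIs in the mutant library. Gene positions came from the GENCODE M21 annotation of mm10 by symbol, and 23058 symbols (98.2%) matched a single annotated gene.

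Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9. Nuclei with at least 500 genes and at most 5% mitochondrial counts were kept, which removed none. Scrublet, as held in scanpy, was run per library with an expected rate of 0.8% per 1000 nuclei, and the nuclei it called were left out. Counts were scaled to 10000 per nucleus and log transformed, 2000 variable genes gave 30 principal components, and Leiden clustering at resolution 0.8 used a graph of 15 nearest neighbours, without integration of the libraries. The graph was rebuilt after first runs, from approximate to exact neighbours and then to double precision, to keep results from depending on the processor. Class sizes and gene counts differed somewhat between those runs, which were not kept.

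Clusters were named from marker lists of 14 cell classes. A cluster carried mDA markers when at least 50% of the 16 reached 20% of their level in the highest cluster of at least 30 nuclei. A cluster with at least 2 glial or vascular markers among the 10 genes that led it over other clusters was named mixed if it carried mDA markers and after the glial class if not. Of the rest, a cluster was named shallow when its nuclei of a library, at least 10 of them, had a median depth under 1/3 of that library's. A cluster with mDA markers was named mDA-like unless another class had more leading markers than the mDA class, and then stayed unnamed. All remaining clusters were named other neurons. The naming rule and its limits were set after the data were seen and went through 3 versions, which gave 896, 1067 and 898 wt and 1888, 2645 and 2237 mutant mDA-like nuclei. The last was adopted after gene counts under the one before had been seen, because clusters led by markers of other classes were not to stay in a compared class. The mDA-like nuclei were clustered again at resolution 0.4, with 0.8 as an alternative. A subcluster was called nigral-type by its mean log2 fold over the other mDA-like nuclei. That fold had to be higher for the substantia nigra list than for the ventral tegmental list. This rule was also set after the data were seen.

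UMI counts were summed over the nuclei of a class per library and divided by the class total of the library to give CPM. The log2 ratio of mutant to wt library was taken with a pseudocount of 5 CPM, for genes with at least 50 UMIs over both libraries (10 for members of gene lists). Genes were counted as higher or lower at 2-fold and 4-fold, and members of lists at 1.5-fold, all with the pseudocount. Folds of single genes and of summed lists are ratios of CPM without a pseudocount, with exact 95% intervals from the binomial split of the counts, which cover counting error only. Where the wt library had 0 UMIs, the fold was taken against 3 counts over the compared nuclei and is a lower bound. With 1 library per genotype no test was run and no p-value is given. A list's median was ranked among 10000 random lists of the same size drawn from 50 bins of mean expression. Medians with genes at their bound have no pseudocount. For shares of nuclei with a tag each nucleus was thinned to 2000 UMIs without replacement, and intervals are exact binomial; where no nucleus had a tag, the share allowed is that of 3 nuclei. The comparison was tested on simulated data in which 200 of 15231 genes were altered: intervals covered the true value for 95.5%, 0 of 15031 unaltered genes met the 2-fold rule, and 87.5% of genes raised and 55% of genes lowered 4-fold did. Genes altered by exactly 2-fold mostly missed it (2.5% found), so these counts are low where levels are low. The simulated libraries shared 1 profile and differed by counting error and the altered genes alone. They say nothing of differences in batch, mice or cluster make-up.

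The gene lists, cell class markers, thresholds, comparisons, alternatives and the rule for named genes were chosen before the data were examined; the alternatives named as added, the naming rule and the exceptions named in the text were not. Named genes are Eed, Ezh2, Suz12, Th, Slc6a3, Slc18a2, Ddc, Nr4a2, Pitx3, Foxa2, Lmx1b and En1, the 12 highest and 12 lowest by log2 ratio in mDA-like nuclei, and at most 4 members of each list with the largest log2 ratio in either direction, among genes with at least 50 UMIs. The 28 lists were PRC2 subunits / PRC1 and H3K27 demethylases / dopamine synthesis, storage and uptake / midbrain dopamine neuron regulators / substantia nigra-type dopamine neuron genes / ventral tegmental-type dopamine neuron genes / Hox genes / other homeobox developmental regulators / non-homeobox developmental regulators / cell cycle inhibitors and p53 response / serotonergic and noradrenergic genes / GABA, glutamate and acetylcholine transmission / neuropeptides / voltage-gated sodium, calcium and HCN channels / potassium channels / dopamine and autoreceptor signalling / synaptic vesicle release / axon guidance and adhesion / nuclear-encoded respiratory chain / mitochondrial genome transcripts / unfolded protein and integrated stress response / heat shock and immediate early genes / Parkinson disease genes / cholesterol synthesis / ribosomal proteins / imprinted genes / housekeeping reference / sex-linked genes. The lists were written from general knowledge of these gene families.

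Alternatives chosen beforehand were at least 1000 genes per nucleus, no filter, doublets kept, Leiden resolutions of 0.4 and 1.6, 15 principal components (for class shares), all nuclei or all neuron-like classes, TMM scaling, median ratio size factors, equal weight per nucleus, nuclei thinned to 2000 or 1000 UMIs, a pseudocount of 1 CPM, and minimum counts of 10 and 200 UMIs. Those added after the data were seen were the earlier naming rules, another seed, the unnamed mDA-marker clusters added, clusters with under 50 nuclei of a library or the cluster of highest depth left out, nuclei at or below the median depth, and subclusters weighted equally. Left out of the comparisons were mixed and unnamed clusters, which carry mDA markers but did not meet the rule for mDA-like nuclei, and classes with under 50 nuclei of a library, except oligodendrocyte-like nuclei as a background. Raw reads were not used here.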

Results

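Nuclei were isolated from adult mouse midbrain, sorted and profiled by single-nucleus RNA sequencing with the 10x Single Cell 3' v3 chemistry, which counts tags near the 3' end of transcripts. The labels name the cell type as midbrain dopaminergic (mDA) neurons and give 2 genotypes, wild type (wt) and a Polycomb repressive complex 2 (PRC2) mutant, of a strain whose name joins a dopamine transporter Cre driver with Eed. PRC2 is the complex that methylates lysine 27 of histone H3 at silenced genes, and Eed is one of its core subunits. The 8 samples are 4 sequencing lanes of each of 2 libraries, and each library pools 2 female mice and 1 male mouse aged 8 months. There was thus 1 library per genotype and no replicate, so no test of a genotype difference was possible, and genotype and batch cannot be told apart. Values are those of these libraries, intervals are 95% intervals for counting error only, and the mutant library is the one labelled as mutant. The comparison asks what mDA nuclei transcribe without functional PRC2.

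The wt library held 1772 nuclei with 46540890 unique molecular identifiers (UMIs), a median of 21532.5 UMIs and of 5209 genes per nucleus. The mutant library held 3968 nuclei with 88201326 UMIs, a median of 17860 UMIs and of 4894.5 genes per nucleus. After doublet calling 1762 wt and 3967 mutant nuclei remained. The caller marked only 10 and 1 nuclei, 0.564% and 0.0252%, so it did not work here and doublets remain in the table.

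Clusters of both libraries together were named by marker genes, and each class is called by its likeness because the sort, not the tissue, sets the shares. The mDA-like class held 898 wt nuclei (51.0%, exact binomial interval 48.6 to 53.3%) and 2237 mutant nuclei (56.4%, 54.8 to 57.9%). These shares moved with the clustering resolution, to 44.1% of wt and 39.4% of mutant nuclei at resolution 0.4. Other neurons made up 181 wt nuclei (10.3%) and 475 mutant nuclei (11.97%). Oligodendrocyte-like nuclei numbered 33 (1.87%) and 47 (1.18%). Clusters led by glial or vascular markers that also carried mDA markers held 352 wt nuclei (20.0%) and 540 mutant nuclei (13.6%). Unnamed clusters with mDA markers held 252 (14.3%) and 633 (16.0%), and an unnamed shallow cluster held 46 (2.61%) and 35 (0.882%). Some mDA-like clusters came almost wholly from 1 library, while others held nuclei of both. Of the wt nuclei, 383 were in cluster 4, beside 6 mutant nuclei. Of the mutant nuclei, 349 were in cluster 23 and 294 in cluster 19, beside 2 and 4 wt nuclei. A cluster taken mostly from 1 library may stand for that library instead of a cell type.

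In mDA-like nuclei the mutant library had far higher levels of transcription factors that pattern the embryo. Of 15 genes for making, storing and taking up dopamine, 7 were at least 1.5-fold lower, Th, Slc6a3 and Slc18a2 among them. En1 and Pitx3, 2 of 14 regulators of the dopamine neuron, were lower too, and Gad1, Gad2 and Slc32a1, genes of GABA transmission, were higher. The sums compared were 25992988 wt and 50801948 mutant UMIs from nuclei with medians of 24988 and 18844 UMIs, expressed as CPM, the counts of a gene scaled by the total of the class in that library. At this depth 1 UMI was 0.0385 CPM in the wt and 0.0197 CPM in the mutant library. Of 15231 genes with at least 50 UMIs, 187 were at least 2-fold higher and 64 at least 2-fold lower in the mutant library, with a pseudocount of 5 CPM. At 4-fold, 60 were higher and 4 were lower. The 2-fold counts depend on the pseudocount, with 468 higher and 197 lower at 1 CPM. The lower genes also depend on clusters drawn mostly from 1 library. Without clusters of under 50 nuclei of a library, 164 of the 187 higher but only 33 of the 64 lower genes were still counted, and with subclusters weighted equally 153 and 38 were. In simulated data the rule found 87.5% of genes raised 4-fold and 55% of those lowered 4-fold, so it finds raised genes more readily. The median log2 ratio of all measured genes was 0.04.

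Eed (chromosome 7, 89954654 to 89980983, minus strand; all positions are in build mm10) is the gene named in the strain. Its level was 21.5 and 42.5 CPM in the wt and mutant library, 1.98-fold higher in the mutant library (interval 1.80 to 2.18). The part of Eed that was deleted is not given in the sources used here, and the counts do not show which exons the tags come from, so this level does not check the genotype label. In other neurons Eed was 18.8 and 25.5 CPM, 1.35-fold higher (1.05 to 1.75). Ezh2, which encodes the methyltransferase of the complex, had 19.7 and 21.6 CPM, and Suz12, a core subunit, had 57.1 and 70.5 CPM. Of 12 PRC2 subunit genes measured, 1 was at least 1.5-fold higher (Eed), 0 were lower and 11 lay within 1.5-fold. Their median log2 ratio was 0.10, at percentile 84.8 among medians of 10000 random lists of genes of like expression, a rank that describes these libraries and is no test. The companion complex PRC1 binds the mark that PRC2 sets, and demethylases of the KDM6 family remove it. Of 21 such genes 6 were higher and 0 lower, with a median of 0.24 (percentile 100). Pcgf5 had 47.6 and 95.04 CPM, Pcgf1 3.04 and 10.2 CPM and Bmi1 5.19 and 11.0 CPM in the wt and mutant library.

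Hox genes set position along the body axis in the embryo and mark hindbrain and spinal cord, not midbrain. Of 28 Hox genes measured out of 31 in the table, 19 were at least 1.5-fold higher in the mutant library, 0 were lower and 9 lay between. All Hox genes together had 2 UMIs in the wt library (0.0769 CPM), so none could be counted as lower. Their median log2 ratio was 1.30 (percentile 100), and 5.98 without the pseudocount and with genes at 0 counts set to their lower bound. Hoxc4 (chromosome 15, 103018934 to 103036852, plus strand) had 0 UMIs in wt mDA-like nuclei and 129.8 CPM in the mutant library, at least 1125-fold higher against a floor of 3 counts (0.115 CPM). Hoxc5 (chromosome 15, 102967443 to 103017429, plus strand) had 0 UMIs and 119.6 CPM, at least 1036-fold higher. The annotated Hoxc5 gene spans Hoxc6 and ends shortly before Hoxc4 on the same strand, so the split of tags among these genes is uncertain. Hoxb6 had 0 UMIs and 50.9 CPM, at least 441-fold higher, and Hoxb3 had 1 UMI and 56.6 CPM, a ratio of 1471 (264 to 58121.5).

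Other homeobox regulators were higher too, with 53 of 94 measured members higher, 1 lower and 40 within 1.5-fold. Their median was 0.73 (percentile 100), or 4.51 with genes at 0 at their bound and no pseudocount. Pax3 (chromosome 1, 78101267 to 78197134, minus strand), a factor of the dorsal neural tube, had 1 UMI in the wt library (0.0385 CPM) and 111 CPM in the mutant library, a ratio of 2889 (518 to 114141). Pax2 had 0.231 and 57.7 CPM, 250.1-fold higher (115 to 682), Pax6 0.462 and 51.6 CPM, 112-fold higher (63.8 to 216), and Onecut2 9.96 and 181 CPM, 18.1-fold higher (16.0 to 20.6). The lower member was Uncx, which wt mDA-like nuclei transcribe, at 19.9 and 7.44 CPM. Among developmental regulators without a homeobox, 36 of 60 were higher, 0 lower and 24 within 1.5-fold, with a median of 0.86 (percentile 100), or 4.79 at the bound. Tbx15 had 1.27 and 70.6 CPM, 55.6-fold higher (39.5 to 80.9), and Gata4 0.462 and 56.1 CPM, 121-fold higher (69.4 to 235). Sim2 had 0.192 and 44.3 CPM, 231-fold higher (98.6 to 711), and Tbx5 had 0 UMIs and 37.5 CPM, at least 325-fold higher. Of the 187 genes at least 2-fold higher, 80 belonged to these 3 regulator lists (42.8%), which hold 149 of all measured genes (0.978%). None of the 64 lower genes did: Uncx lay just short of that size with the pseudocount. A gene under 5 CPM in the wt library cannot be 2-fold lower with a pseudocount of 5 CPM. The lack of lower regulators thus means little for members near 0 in the wt library. Summed over the 3 lists, regulators made up 197 CPM in the wt and 2266 CPM in the mutant library, 11.5-fold higher (11.2 to 11.8).

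**Figure D1:**
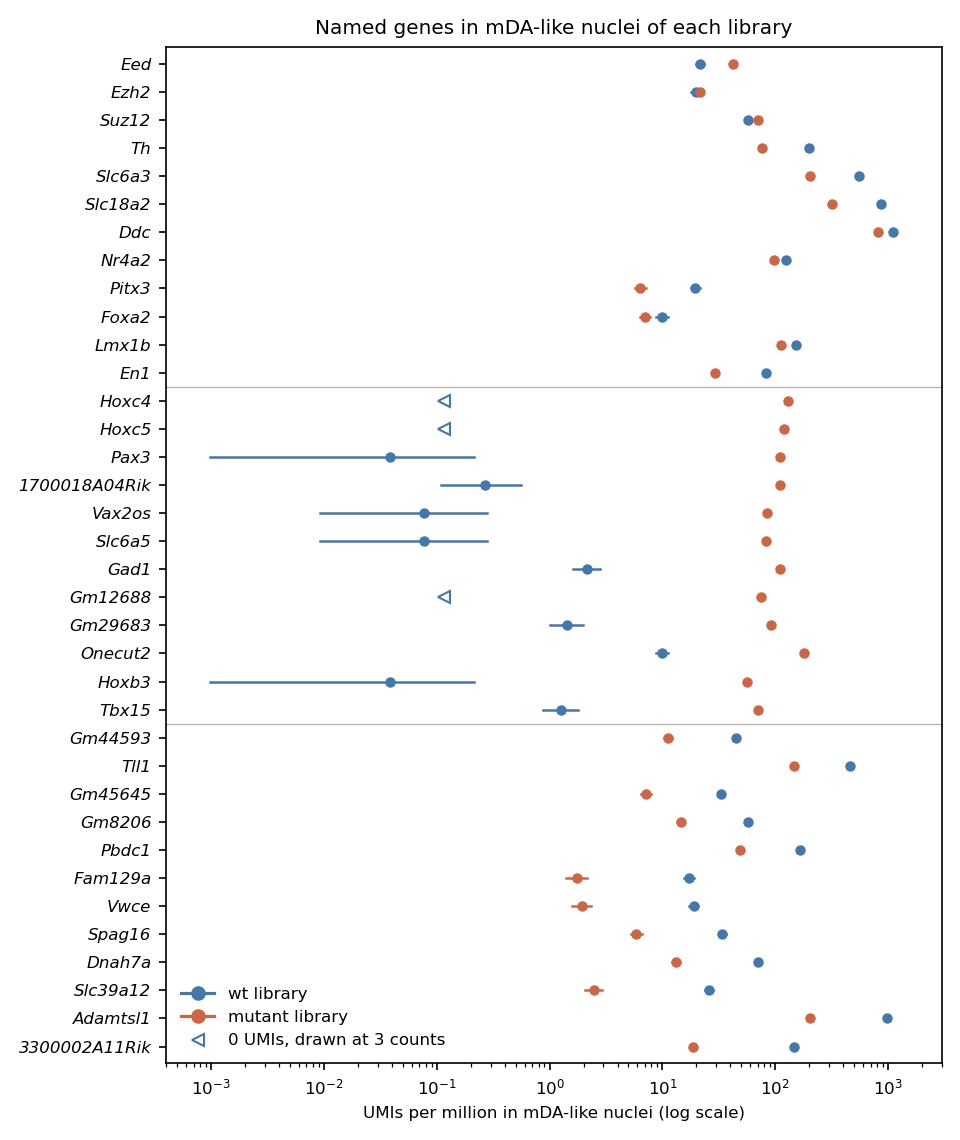
Level of 36 genes in mDA-like nuclei of the wt and mutant library, in CPM on a log axis, with 95% counting intervals; open triangles mark 0 UMIs, drawn at 3 counts. Hoxc4, Hoxc5 and Gm12688 had 0 UMIs in the wt library, and Th, Slc6a3 and Slc18a2 were lower in the mutant library.

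Cdkn2a (chromosome 4, 89274471 to 89294653, minus strand) and its neighbour Cdkn2b encode inhibitors of cell cycle kinases and are silenced by Polycomb in many cell types. Cdkn2a had 0 UMIs in wt mDA-like nuclei and 19.8 CPM in the mutant library, at least 172-fold higher. Cdkn2b had 0 UMIs and 4.92 CPM, at least 42.6-fold higher. These were the 2 higher members among 21 cell cycle inhibitors and p53 response genes, 0 were lower, and the median was 0.12 (percentile 99.8). Pmaip1, which promotes cell death, had 1 UMI and 1.97 CPM, a ratio of 51.2 (8.98 to 2041).

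The share of mDA-like nuclei with a tag was compared after every nucleus was thinned to 2000 UMIs, with 3 shallower wt and 9 shallower mutant nuclei left out and 895 and 2228 kept. A tag of Hoxc4 was found in 0 wt nuclei, which allows up to 0.335%, and in 17.0% of mutant nuclei (15.5 to 18.6%). Without thinning the mutant share was 60.9%. For Pax3 the shares were 0% and 16.4% (0.111% and 57.0% without thinning). For Gad1 they were 0.447% and 16.9% (3.45% and 68.6%), and for Onecut2 2.12% and 29.8%. Th was found in 31.8% of wt and 15.8% of mutant nuclei (93.0% and 71.4% without thinning), Slc6a3 in 59.1% and 31.9% (94.0% and 81.4%) and Slc18a2 in 77.3% and 46.0% (99.2% and 94.5%). Background from free RNA was read in oligodendrocyte-like nuclei, with medians of 3490 and 2768 UMIs before thinning, against 24988 and 18844 in mDA-like nuclei. Among 30 wt and 34 mutant oligodendrocyte-like nuclei, after 3 and 13 shallower ones were left out, 0 had a tag of Hoxc4, Pax3 or Th, which allows up to 10% and 8.82%. Gad1 was found there in 0% and 2.94%, Slc6a3 in 6.67% and 0%, and Onecut2 in 10% and 11.8%. Hoxc5 and Tbx15 were each found in 0% and 2.94%. Ddc, an mDA marker, was found in 20% and 20.6%, against 83.9% and 77.8% of mDA-like nuclei, so some background of mDA RNA is present. The wt share of Onecut2 was 0.313% (up to 1.73%) in nigral-type mDA nuclei and 3.13% (1.86 to 4.89%) in other mDA nuclei. Nigral-type names subclusters whose fold over the other mDA-like nuclei was higher for substantia nigra-type than for ventral tegmental-type genes. The background for this gene rests on 3 of 30 nuclei (2.11 to 26.5%), so how much of the wt share is background is left open.

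Th (chromosome 7, 142892752 to 142931128, minus strand) encodes tyrosine hydroxylase, the first enzyme of dopamine synthesis. Its level was 199.5 and 76.7 CPM in the wt and mutant library, 2.60-fold lower in the mutant library (2.496 to 2.71). Slc6a3 (chromosome 13, 73536747 to 73578672, plus strand), the dopamine transporter gene that also drives Cre in this strain, had 550.3 and 205 CPM, 2.69-fold lower (2.62 to 2.75). Slc18a2 (chromosome 19, 59260896 to 59296012, plus strand), which encodes the vesicular monoamine transporter, had 859.5 and 319 CPM, 2.70-fold lower (2.64 to 2.75). Ddc, which encodes the next enzyme of the pathway, was 1.35-fold lower (1.33 to 1.37), at 1109.7 and 821 CPM. Of 15 genes of dopamine synthesis, storage and uptake, 0 were higher, 7 lower and 8 within 1.5-fold, with a median of -0.50 (percentile 0) and of -0.66 without the pseudocount. Aldh1a1, an aldehyde dehydrogenase of ventral nigral neurons, had 204 and 96.5 CPM, and Gch1, needed for the cofactor of tyrosine hydroxylase, had 39.2 and 18.8 CPM.

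En1 (chromosome 1, 120602418 to 120607992, plus strand), a homeobox factor that adult dopamine neurons need to survive, had 83.2 and 29.5 CPM, 2.82-fold lower in the mutant library (2.64 to 3.01). Pitx3 (chromosome 19, 46135685 to 46148326, minus strand), a homeobox factor of mDA neurons, had 19.6 and 6.38 CPM, 3.08-fold lower (2.67 to 3.55). Nr4a2, which activates Th and Slc6a3, was 1.27-fold lower (1.21 to 1.32) in the pooled nuclei, at 124 and 97.6 CPM; in subcluster 2 of the mDA-like nuclei it was higher. Lmx1b had 152 and 112 CPM and Foxa2 9.89 and 7.05 CPM, 1.36-fold (1.30 to 1.41) and 1.403-fold lower (1.19 to 1.65). Of 14 regulators of mDA neurons, 0 were higher, 2 lower (En1 and Pitx3) and 12 within 1.5-fold, with a median of -0.30 (percentile 0.01). Levels of En1 and Pitx3 were lower in other neurons as well. In other neurons En1 had 13.7 and 6.01 CPM, 2.27-fold lower (1.58 to 3.26). Pitx3 was 3.52-fold lower there, on only 10 and 8 UMIs. The list had a median of -0.06 in other neurons (percentile 19.8), with 13 of 14 members within 1.5-fold. Whether a library difference common to both classes lowered En1 and Pitx3 was not tested. RNA of mDA nuclei in the droplets of other neurons would give the same falls, so other neurons do not settle this.

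Genes of substantia nigra-type dopamine neurons were lower, with 7 of 11 members lower and 0 higher, a median of -0.80 (percentile 0) and of -1.08 without the pseudocount. In mDA nuclei outside the nigral-type subclusters 3 of 11 were lower and the median was -0.39 (percentile 0). Its interval over the members, -1.29 to 0.08, includes 0. The split was made after the data were seen and uses this same list. Of the 320 wt nigral-type nuclei 319 were in subcluster 1, beside 10 mutant nuclei, so nigral-type nuclei of the libraries are unlike and give no reading of this list. The pooled median of -0.80 may thus reflect the share of subcluster 1 in each library. Ndnf had 93.5 and 33.5 CPM, Anxa1 16.6 and 4.11 CPM and the growth factor gene Igf1 115 and 52.7 CPM. Genes of ventral tegmental-type neurons had a median near 0, 0.03 (percentile 51.1), which was -0.03 with doublets kept, and 2 of 13 were higher (Nfix and Slc32a1) and 2 lower (Tacr3 and Calb1). Tacr3, a tachykinin receptor gene, had 118 and 49.0 CPM, and Calb1, a calcium-binding protein gene, 82.0 and 51.8 CPM.

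Gad1 (chromosome 2, 70553072 to 70602014, plus strand), which encodes the main enzyme of GABA synthesis, had 2.15 and 109.9 CPM, 51.0-fold higher in the mutant library (39.2 to 67.6). Gad2, the second such enzyme, had 10.1 and 60.4 CPM, 5.96-fold higher (5.26 to 6.79), and Slc32a1, the vesicular transporter for GABA and glycine, 0.692 and 6.32 CPM, 9.12-fold higher (5.68 to 15.6). Slc6a5, the glycine transporter gene of inhibitory hindbrain and spinal neurons, had 2 UMIs in the wt library and 81.9 CPM in the mutant library, a ratio of 1065 (295 to 8795). These were the 4 higher members among 13 genes of GABA, glutamate and acetylcholine transmission, 0 were lower, and the median was 0.29 (percentile 100). Of 7 serotonergic and noradrenergic genes in the table only 3 were measured, 3 within 1.5-fold, with a median of -0.06 (percentile 9.46) that was 0.02 with at least 1000 genes per nucleus, 0.0085 over all nuclei and 0.01 over all neuron-like classes; Tph2, the enzyme gene of serotonin synthesis in the brain, had 29 and 30 UMIs. Among 21 neuropeptide genes 1 was higher (Vgf, 2.65 and 7.97 CPM) and 0 were lower, with a median of 0.04 (percentile 90.8) that was -0.04 when nuclei were thinned.

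Pacemaker firing of dopamine neurons rests on sodium, calcium, potassium and HCN channels. The 27 sodium, calcium and HCN channel genes measured had a median of 0.06 (percentile 69.6), which was -0.02 with thinning. Among 39 potassium channel genes 3 were higher (Kcna1, Kcnn2 and Kcnip1), 2 lower (Kcnj6 and Kcnn3) and the median was 0.11 (percentile 94.8). Kcnn2 had 207 and 369 CPM, Kcna1 5.001 and 14.2 CPM and Kcnj6, the channel that dopamine autoreceptors open, 1151 and 657 CPM. Dopamine and autoreceptor signalling had 3 of 26 members lower (Oprk1, Ntsr1 and Tacr3), 0 higher and a median of 0.01 (percentile 15.1), which was -0.01 with TMM scaling. The autoreceptor gene Drd2 had 353 and 248 CPM, Oprk1 143 and 74.997 CPM and Ntsr1 80.7 and 43.0 CPM. In synaptic vesicle release 5 of 36 were lower (Sv2c, Cplx1, Erc2, Cadps2 and Rims1), 0 higher, and the median was 0.10 (percentile 79.4). Sv2c had 637 and 261 CPM and Cplx1 159.5 and 66.9 CPM. Axon guidance and adhesion genes had a median of -0.19 (percentile 0), with 4 of 48 higher and 4 lower. The higher ones were Slit3 at 56.1 and 101 CPM, Nrp1 at 21.9 and 41.0 CPM, Ephb1 and Sema5a, and Epha3 at 112 and 65.3 CPM was among the lower ones. Uncx, Kcnn3, Rims1 and Sema5a were named after their values were seen.

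Cholesterol synthesis genes were lower as a group in mDA-like nuclei, with 11 of 20 lower, 0 higher, a median of -0.67 (percentile 0) and of -0.82 without the pseudocount. Fdft1 had 76.8 and 38.2 CPM, Sqle 28.1 and 13.2 CPM and Msmo1 49.7 and 25.3 CPM. Transcripts of the mitochondrial genome had a median of -0.42 (percentile 0), with 1 of 12 lower (mt-Nd2, 36.9 and 18.0 CPM) and 0 higher. Nuclei hold no mitochondria, so these tags come from cytoplasm carried along. Nuclear genes of the respiratory chain had a median of 0.15 (percentile 99.99), with all 54 measured genes within 1.5-fold. Heat shock and immediate early genes, which report stress and activity, had 4 of 19 members higher (Nr4a3, Nr4a1, Fosl2 and Npas4), 0 lower and a median of 0.17 (percentile 99.97). Nr4a3 had 3.69 and 32.4 CPM, 8.77-fold higher (7.13 to 10.9), and Nr4a1 9.62 and 30.4 CPM, 3.16-fold higher (2.77 to 3.63). Cluster 16 of the mDA-like class, with 30 wt and 199 mutant nuclei, had Fos, Fosb and Nr4a3 among its 10 leading genes; Fos and Fosb were named after their values were seen. Without clusters of under 50 nuclei of a library, this one included, the log2 ratio was 2.18 for Nr4a3 and 1.23 for Nr4a1, against 2.10 and 1.28. Among genes of the unfolded protein and integrated stress responses, all 28 lay within 1.5-fold, with a median of 0.03 (percentile 62.7); Ddit3, a death factor of that response, had 11.5 and 6.97 CPM and the chaperone gene Hspa5 11.3 and 13.8 CPM.

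Among Parkinson disease genes 3 of 21 were lower (Gch1, Sncaip and Pla2g6), 0 higher, and the median was -0.02 (percentile 4.41). Of 18 imprinted genes 1 was higher (Nap1l5, 44.2 and 72.0 CPM) and 0 lower, with a median of 0.14 (percentile 97.0). All 39 ribosomal protein genes lay within 1.5-fold, and their median was 0.05 (percentile 77.7), or -0.01 when each nucleus had equal weight. All 25 housekeeping genes also lay within that range, with a median of 0.08 (percentile 74.4). The 6 sex-linked genes had a median of -0.21 (percentile 1.08), with 6 within 1.5-fold. Xist, of the silenced X chromosome in females, had 702 and 833 CPM and Y-linked Eif2s3y 9.62 and 7.44 CPM. Xist and its antisense gene Tsix overlap, so the split of tags between them is uncertain.

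**Figure D2:**
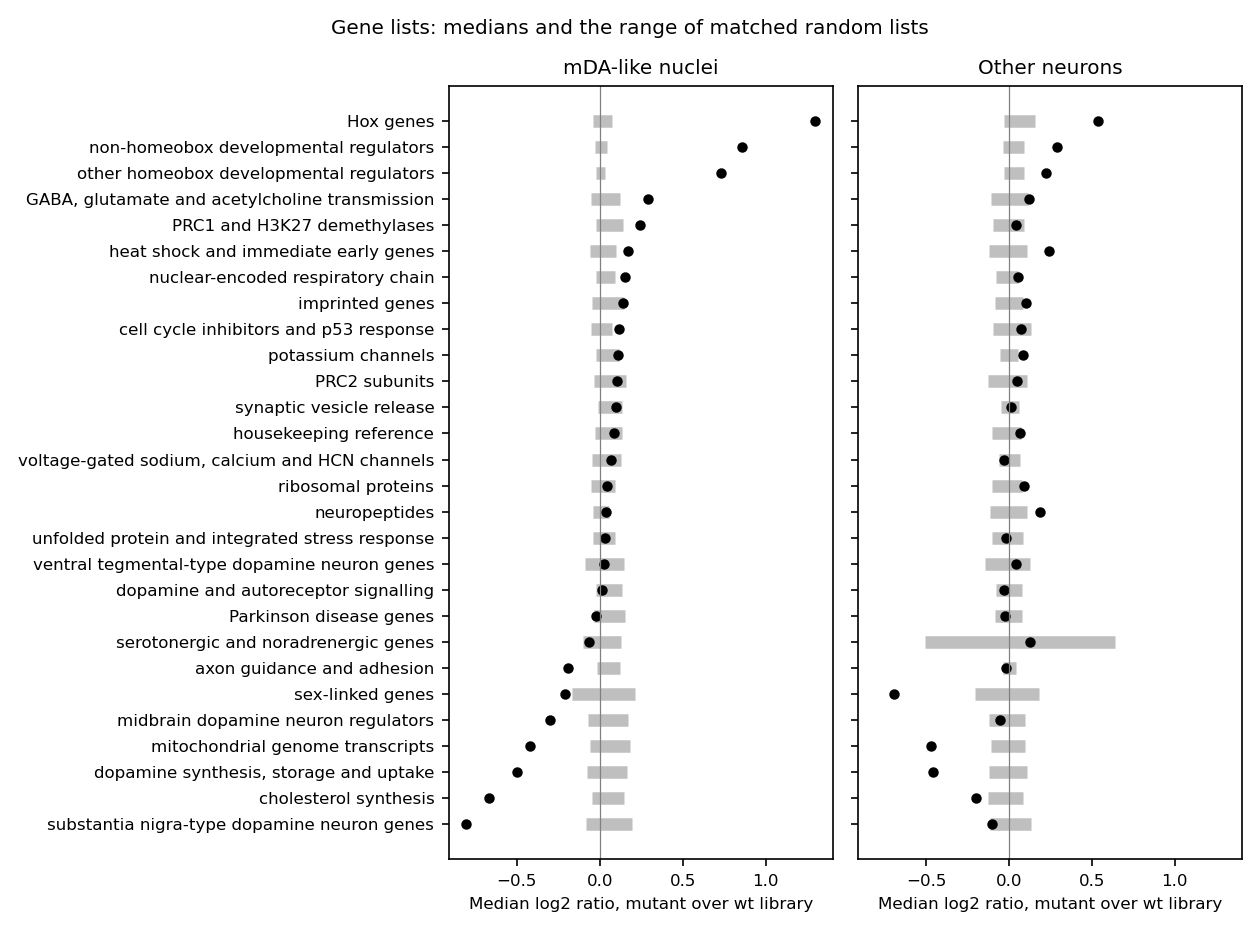
Median log2 ratio (mutant over wt library) of the 28 gene lists as black dots, in mDA-like nuclei on the left and other neurons on the right; grey bars span the central 95% of medians of random lists of like expression. In mDA-like nuclei Hox genes had the highest median (1.30) and substantia nigra-type genes the lowest (-0.80).

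The 12 genes with the highest ratio in mDA-like nuclei were Hoxc4, Hoxc5, Pax3, 1700018A04Rik, Vax2os, Slc6a5, Gad1, Gm12688, Gm29683, Onecut2, Hoxb3 and Tbx15. Little is known of 1700018A04Rik (7 and 5624 UMIs), Vax2os (2 and 4306 UMIs), Gm12688 (0 and 3760 UMIs) and Gm29683 (37 and 4619 UMIs); Vax2os is a long noncoding RNA that lies opposite the homeobox gene Vax2. None of the 12 lowest genes was in the regulator lists. The lowest, 3300002A11Rik, had 148 and 18.6 CPM, 7.95-fold lower (7.40 to 8.55), and Adamtsl1 (chromosome 4, 85514172 to 86428385, plus strand), which encodes a secreted matrix protein, had 972 and 204 CPM, 4.78-fold lower (4.67 to 4.89). Slc39a12, a zinc transporter gene, had 26.0 and 2.46 CPM, 10.6-fold lower (8.71 to 12.9). Dnah7a and Spag16, genes of motile cilia, had 70.2 and 13.2 CPM and 34.0 and 5.89 CPM, and the protease gene Tll1 had 464 and 148 CPM. 3300002A11Rik, Adamtsl1 and Tll1 were among the 10 leading genes of cluster 4 (383 wt and 6 mutant nuclei), as were Ndnf, Anxa1, Sv2c and Slc6a3. Their pooled folds may reflect the share of that cluster in each library. The other genes among the 12 lowest were Vwce, Fam129a, Pbdc1, Gm8206, Gm45645 and Gm44593. Gm45645 lies within Erc2 on the other strand, so tags of both are uncertain.

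Marker lists of cell classes were read in the same mDA-like nuclei. GABAergic neuron markers, 7 of 11 higher and 0 lower, had a median of 0.99 (percentile 100). Glutamatergic neuron markers, 5 of 10 higher, had a median of 0.56 (percentile 100). Both lists overlap the transmission list and the regulator lists. The mDA markers, 8 of 16 lower and 0 higher, had a median of -0.68 (percentile 0). Medians of the other lists were 0.17 (percentile 97.1) for serotonergic neurons, 0.30 (percentile 99.9) for cholinergic neurons, 0.06 (percentile 88.0) for medium spiny neurons, 0.09 (percentile 98.4) for oligodendrocytes, 0.05 (percentile 93.4) for their precursors and 0.05 (percentile 95.5) for astrocytes. They were -0.20 (percentile 0) for microglia and macrophages, -0.14 (percentile 1.05) for endothelium, -0.03 (percentile 17.0) for pericytes, smooth muscle and fibroblasts, 0.00 (percentile 47.1) for ependyma and choroid and -0.14 (percentile 0.675) for T or B cells.

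To see whether the difference lay in particular mDA subtypes, mDA-like nuclei were clustered again into 10 subclusters, and the 6 with at least 50 nuclei of each library were compared one by one. The regulator lists were higher and the dopamine genes lower in each of these 6 subclusters. None of the 6 was nigral-type, so they do not show how nigral-type subclusters compare. Summed regulators were 4.65 to 12.02-fold higher in the mutant library, at 118 to 318 CPM in the wt and 1421 to 2273 CPM in the mutant library. Hox genes had medians of 1.09 to 2.23. Th was 1.98 to 3.81-fold lower, Slc6a3 1.39 to 3.85-fold, Slc18a2 1.83 to 3.09-fold and Ddc 1.14 to 1.41-fold lower. En1 was 1.52 to 2.72-fold lower. Pitx3 was up to 4.48-fold lower, in subcluster 5 (1.83 to 13.2). In subcluster 0 its wt level was 0.979 times that of the mutant library, with a wide interval (0.143 to 5.79). Nr4a2 was 1.17 to 1.35-fold lower in 5 of the 6 subclusters, with an interval that includes no difference in 1 of these (0.896 to 1.54). It was 1.33-fold higher (1.15 to 1.55) in subcluster 2. Its mutant level was 0.948 times the wt level in other mDA nuclei (0.894 to 1.004, which includes no difference) and 0.601 times in nigral-type nuclei (0.560 to 0.646). The nigral-type value compares unlike clusters, since wt and mutant nigral-type nuclei come mostly from different subclusters. Eed was 1.47 to 2.27-fold higher. At a finer resolution of 0.8, 6 of 17 subclusters had enough nuclei of both libraries, and summed regulators were 4.66 to 13.9-fold higher there. The other subclusters held too few nuclei of 1 library to be compared.

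**Figure D3:**
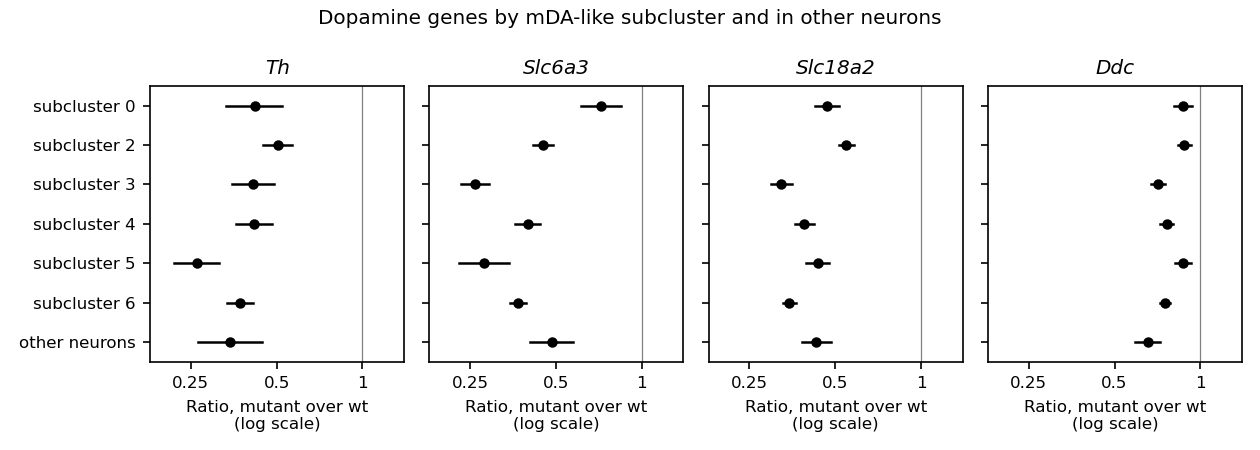
Ratio of the mutant to the wt library for Th, Slc6a3, Slc18a2 and Ddc in the 6 mDA-like subclusters with at least 50 nuclei of each library and in other neurons, with 95% counting intervals. All 4 genes lay below a ratio of 1 in each of the 6 subclusters and in other neurons.

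Other neurons of the same sort served as the comparison within the libraries, since a Cre driven by the dopamine transporter is active in dopamine neurons. There the regulators were higher too, but by far less than in mDA-like nuclei. This class held 181 wt and 475 mutant nuclei. Of 11955 genes measured, 31 were at least 2-fold higher and 18 lower in the mutant library, and at 4-fold 0 were higher and 0 lower. Summed regulators were 457 and 730.2 CPM, 1.598-fold higher (1.52 to 1.68). In oligodendrocyte-like nuclei they were 641 and 789 CPM, 1.23-fold higher with an interval of 0.933 to 1.63 that includes no difference.

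Hox genes in other neurons had 7 of 15 members higher, 0 lower and a median of 0.54 (percentile 100). Summed Hox genes had 7 and 754 UMIs there, or 1.65 and 63.0 CPM, 38.2-fold higher in the mutant library. In mDA-like nuclei they had 0.0769 and 585 CPM. In other neurons Hoxc4 had 0 UMIs in the wt library and 14.4 CPM in the mutant library. Other homeobox regulators had 9 of 55 higher, 1 lower (Isl1) and a median of 0.22 (percentile 100), and those without a homeobox 9 of 43 higher, 1 lower (Sim1) and a median of 0.29 (percentile 100). Gad1 had 62.4 and 68.3 CPM. Dopamine synthesis genes, with 7 of 15 lower, had a median of -0.46 (percentile 0), and Th had 29.4 and 10.1 CPM there, 2.91-fold lower (2.25 to 3.77). Slc18a2 was 2.33-fold (2.07 to 2.62), Slc6a3 2.07-fold (1.74 to 2.46) and Ddc 1.53-fold lower (1.39 to 1.69) in other neurons. Adamtsl1 had 215 and 227.7 CPM, 1.06-fold higher (0.984 to 1.15). Substantia nigra-type genes had a median of -0.10 (percentile 3.89), cholesterol synthesis genes of -0.20 (percentile 0.07) with 1 of 20 lower, and PRC1 and demethylase genes of 0.04 (percentile 81.9). Mitochondrial transcripts had a median of -0.47 (percentile 0) and immediate early and heat shock genes of 0.24 (percentile 100), with 5 of 17 higher. Sex-linked genes had 5 of 6 lower and a median of -0.70 (percentile 0); Eif2s3y had 13.0 and 4.93 CPM there. Isl1 and Sim1 were named after their values were seen.

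**Figure D4:**
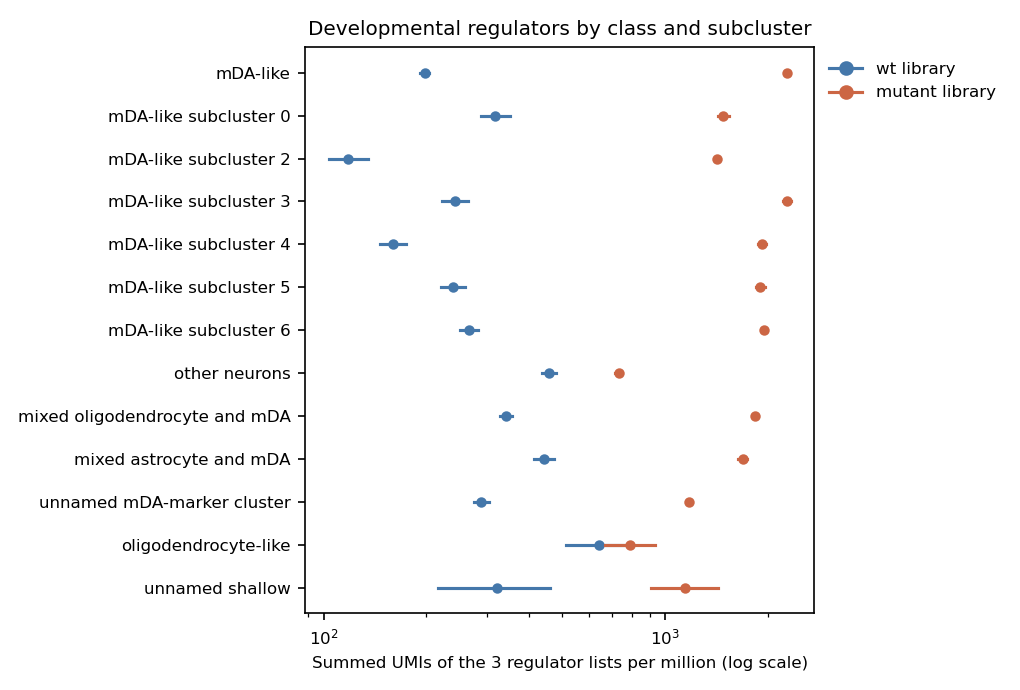
Summed level of the 3 lists of developmental regulators per class and mDA-like subcluster in the wt and mutant library, in CPM with 95% counting intervals. The sum was 11.5-fold higher in mDA-like nuclei and 1.598-fold higher in other neurons.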

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

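Tests on free RNA, on other neurons and on the source of regulators in other neurons were chosen after the results were seen, and those on doublets and depth before. Mixed and unnamed classes were left out of the main comparisons and entered only alternatives such as that over all nuclei. A signal of the same kind was found in them. Summed developmental regulators were 4.04-fold higher in the mutant library in unnamed clusters with mDA markers, 5.37-fold higher in mixed oligodendrocyte and mDA nuclei, 3.82-fold higher in mixed astrocyte and mDA nuclei and 3.56-fold higher in unnamed shallow nuclei. All of these classes carry mDA markers. Igf1, which encodes a growth factor, went opposite ways in the classes compared: mutant levels were 0.458 times wt levels in mDA-like nuclei and 1.85 times in other neurons. That difference between classes was not tested, since each rests on 1 library per genotype.

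Higher developmental regulators in mutant mDA-like nuclei were weighed against technical explanations. In nuclei at or below their library's median depth the fold was still 9.03 (8.58 to 9.51, with 449 wt and 1119 mutant nuclei). That value cannot decide on doublets, since mixed nuclei were not always deep. Mixed astrocyte and mDA nuclei had medians of 6268 wt and 11518 mutant UMIs, against 24988 and 18844 in mDA-like nuclei. Mixed oligodendrocyte and mDA nuclei were deeper, at 32105 and 28622 UMIs. Doublets thus stay open. Lower depth is argued against by nuclei of 15000 to 25000 UMIs, where the fold was 10.3 (9.74 to 11.0). Free RNA and a shift common to every nucleus are argued against by the excess elsewhere, which was 7.14% of that in mDA-like nuclei in oligodendrocyte-like nuclei (-6.26 to 20.2%) and 13.2% in other neurons (11.5 to 14.9%). A loss of PRC2 silencing in the cells that carry the Cre may be the source, a hypothesis that was not tested here. Replicate libraries of each genotype, and the methylation mark at these genes in mDA nuclei of both genotypes, would test it. A batch difference specific to these genes stays open with 1 library per genotype.

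In other neurons the smaller excess of regulators may be RNA of mDA nuclei in those droplets, as free RNA or doublets. Their regulator excess was 13.2% of that in mDA-like nuclei, beside a level of Th, Slc6a3 and Slc18a2 of 14.9% in the mutant and 12.8% in the wt library, a ratio of 0.888 between excess and mutant share. In oligodendrocyte-like nuclei those genes lay at 7.41% and 3.80% of their mDA-like level. Some other neurons that transcribe dopamine genes themselves would give the same ratio, so low Cre activity in them also stays open and was not tested.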

How the results depend on the processing

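Settings with the earlier naming rules, another seed, unnamed clusters added, clusters left out, shallower nuclei or equal subcluster weights were chosen after the data were seen. No paired analysis was possible because each genotype is 1 library, and no library could be left out. Of 1270 values of named genes under planned settings, 943 stayed within their counting interval, 323 moved in the same direction or stayed near 0 and 4 reversed. Under added settings 612, 403 and 1 of 1016 did so. List medians moved in 18 of 362 planned and 5 added values, against 344 and 219 that did not, and none that stood clear of 0 reversed. In subclusters and other neurons 27 of 40 list medians moved, and of shares of nuclei with a tag 70 of 88 moved, as other thinning depths must do. Higher genes made up 70.4 to 77.0% of those counted under every setting, against 74.5%. TMM and median ratio factors were 1.03 and 1.02.

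Over all nuclei 39 genes were lower and other homeobox regulators had a median of 0.47; the cause was not tested. Thinning gave that list 1.22, with fewer genes measured, and reversed Aebp2 (-0.043), Adcyap1 (-0.061), Cox8a (-0.016) and Kdm5d (0.025), and Rpl7 reversed in nuclei at or below the median depth (-0.0063); the cause was not tested. A pseudocount of 1 CPM, which shrinks low levels less, gave 468 higher and 197 lower genes, and medians of 3.05 for Hox genes, 1.93 for other homeobox and 2.28 for non-homeobox regulators. A minimum of 200 UMIs drops the lowest members and gave 1.39 and 1.84 for the latter lists. The minimum counts did not alter the number of higher or lower genes, no filter removed no nucleus, and with 10 UMIs lists have the minimum they already had. The mDA-like share of wt nuclei was 44.1% at resolution 0.4, 43.5% at 1.6, 60.6% with the second naming rule and 48.3% with another seed. The mutant share was 39.4%, 41.2%, 66.7% and 53.2% in turn, 47.4% with at least 1000 genes, 52.5% with 15 components and 47.6% with the first naming rule. Depth limits genes near the floor: 1 UMI is 0.0385 CPM in wt mDA-like nuclei.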

Other observations

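Tests on composition, on other neurons and on batch were chosen after the results were seen, that on depth before, and the comparison of nigral-type nuclei was not planned. Nigral-type nuclei differed more between the libraries than other mDA nuclei. They numbered 320 in the wt and 917 in the mutant library, 35.6% (32.5 to 38.9%) and 41.0% (38.9 to 43.1%) of mDA-like nuclei. The mutant ones were mostly in subclusters 8 and 9 (338 and 569 mutant, 1 and 0 wt nuclei). In these the substantia nigra list had a mean log2 fold over other mDA-like nuclei of -0.27 and 0.08, against 1.33 in subcluster 1. Subcluster 4, at -0.30, counted as other mDA, so the shares depend on the rule. Summed developmental regulators were 154 and 2872 CPM in nigral-type nuclei, 18.6-fold higher in the mutant library, against 7.93-fold in other mDA nuclei. Lef1, Pax3, Hoxc4 and Hoxc5, members of the summed lists, were among the genes that led subclusters 8 or 9. These nuclei may thus have been grouped partly by the genes summed. Of genes at least 2-fold apart, 275 were higher and 127 lower in nigral-type nuclei, and 169 and 51 in other mDA nuclei. En1 had 89.1 and 21.2 CPM in nigral-type and 79.2 and 36.0 CPM in other mDA nuclei of the wt and mutant library. Slc6a3 was 2.96-fold and 2.49-fold lower. Nigral-type nuclei of the libraries come mostly from different subclusters, so the pooled values compare unlike clusters, and the difference between the types was not tested.

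In other neurons the cholinergic markers were lower, 3 of 4 measured, with a median at percentile 0 among random lists. Log2 ratios were -1.05 for Chat, which encodes the enzyme of acetylcholine synthesis, and -1.63 for the choline transporter gene Slc5a7. Among peptide genes Cartpt had -1.99 and Penk 1.48, and the 21 peptide genes had a median of 0.19 (percentile 100). These genes were chosen after their values were seen, and the class mixes neuron types whose shares the sort can alter.

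Lower Th, Slc6a3 and Slc18a2 in mutant mDA-like nuclei were weighed in the same way. With the 6 subclusters of at least 50 nuclei of each library weighted equally, the smallest of the 3 folds was 2.40-fold lower. A lower share of subclusters rich in these genes is thus argued against only among these 6. Subcluster 1, with 319 wt and 10 mutant nuclei, was left out, so the effect of its lower share was not tested. Lower depth is argued against by nuclei of 15000 to 25000 UMIs, where the smallest fold was 2.49 (at least 2.36 by its interval). A library difference that acts on every nucleus stays open: in other neurons, where it should act too, the smallest of the 3 folds was 2.07 (at least 1.74 by its interval), and Th was 2.91-fold and Slc18a2 2.33-fold lower. Mitochondrial transcripts, carried along with nuclei, were lower in both classes as well, with medians of -0.42 in mDA-like nuclei and -0.47 in other neurons. RNA of mDA nuclei in those droplets would give the same fall of the 3 genes, so other neurons do not settle this. A difference in batch or handling specific to these genes cannot be told apart from genotype, as there was 1 library per genotype. Reduced transcription of the dopamine genes without functional PRC2 also stays open and was not tested. Replicate libraries of each genotype, corrected for free RNA with counts from empty droplets, would test it.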
